A study of Zea mays with 9 samples.

How the data were processed

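RNA was measured in 9 tassel samples of maize, 3 from wildtype, 4 from ndl1 and 2 from Bif1;Bif4 plants, all in the B73 background. Per the labels' protocols, field-grown tassels of 2 to 4 mm were snap frozen, total RNA was extracted with a column kit and DNase, and stranded mRNA libraries were made with a TruSeq kit. Trimmomatic, TopHat2 2.1.1, HTSeq and DESeq2 are named in the submitters' processing notes, and the genome build and the strand setting of the counting are not given in the sources used here. Reads of antisense or overlapping genes, and of near-identical copies such as glutathione transferases, heat shock genes, histones and the pair of CPN60I identifiers, are therefore uncertain.

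The deposited data were 1 table per mutant against wildtype, each with 39305 gene identifiers. The signal values per library are normalized counts, which the authors made by dividing the counts of a library by its DESeq2 size factor, per the file headers and the values. The log2 fold changes and their standard errors are the authors' DESeq2 estimates, per the file headers. Each p-value and adjusted p-value column was likewise deposited by the authors from DESeq2, and the test statistic column is the authors' score. In every library 100% of the values were whole multiples of 1 read within 0.1 reads, so that the counts could be recovered from the deposited values. The recovered totals were 16863087 to 22533736 reads per library, and 8117 identifiers had no read in any library. The wildtype reads were the same in both tables, with 0 of 39305 genes differing in any of the 3 libraries. Same-group library pairs differed beyond counting noise, with a chi-square per degree of freedom of 9.80 to 40.1, so that no library was counted as a copy of another.

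Gene names came from the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which was used only for names and for which genes neighbour each other. Of the identifiers, 18475 matched 1 RefSeq gene and 521 several, and 2516 had a descriptive name. The groups, the tests, the named-gene rule, the gene lists and most of the other settings tried were fixed before the data were examined. As planned for size-factor normalized values, the test was limma (3.58.1, R 4.3.3) with an intensity trend on log2(normalized count + 1), fitted to each table separately, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of group means on this scale. The added 1 shrinks the change of genes with low counts. A mean of log values can still give a larger change than the mean counts do, as for ra3 in Bif1;Bif4. Genes with few reads were removed with edgeR's filterByExpr at its minimum count of 10 on the recovered reads, a filter chosen once the unit was known and before any call was seen. Levels of the named genes are given as mean ± SD of the normalized counts of the table concerned, and fold changes with their standard error. The recovered reads were also tested with edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0). The labels do not say that the libraries came from separate plants or plots, so p-values measure only the spread between these samples, which may be technical.

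In all 14 gene lists were used. They covered mitochondrial stress and proteases, the respiratory chain, heat shock and chaperones, the auxin pathway, inflorescence regulators, floral MADS box genes, the cell cycle, histones, cytosolic ribosomal proteins, photosynthesis, vascular and secondary wall genes, oxidative stress and detoxification, stress hormones and defence, and anther and meiosis genes. Because the reference holds no product descriptions, members were matched by gene name once the tables could be read and before fold changes were examined. Each list with at least 3 tested members, 13 of the 14, was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. With an estimated correlation 0 lists passed in either comparison, against 2 in ndl1 and 1 in Bif1;Bif4 at an unadjusted p under 0.05. Named genes were the mutated genes, the 10 largest rises and 10 largest falls among called genes with a mean normalized count of at least 50, a descriptive name and no overlap between groups. To these were added up to 4 members per list with the lowest adjusted p, all inflorescence and auxin members given by symbol, and genes called in both comparisons. Further list members that passed are named beside their list's count, chosen after their values were seen. The text gives only part of the genes that this rule names, and the others are not reported here.

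Overlap between the mutants was set beside 20 simulated pairs of unchanged mutants that shared the wildtype libraries and 100 such pairs with correlated genes, which were added after the first 20 had been seen. A direct comparison of the mutants used the 9 libraries scaled together. A group with no read was given a floor of 3 reads over the group, and 95% intervals of read ratios cover counting error only. Alternatives covered the tool, the scaling, the filter (none, or a mean normalized count of at least 10), pseudocounts of 0.5 and 4, adjusted p 0.01, an absolute log2 fold change of at least 1, all groups in 1 fit, a replicate block and leaving out each library.

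The procedure was tested on simulated data with 200 changed genes in each of 5 draws. For ndl1 against wildtype (22213 to 22245 genes run) limma recovered 58.6% of genes changed 2-fold and 88% of genes changed 4-fold, and 6.95% of its calls were unchanged genes. For Bif1;Bif4 against wildtype (22126 to 22156 genes run) it recovered 60.4% and 88%, and 11.1% of its calls were unchanged genes. The mean share of false calls thus lay above the nominal 5% in both. Single draws ran from 4.79% to 9.04% in ndl1 and from 8.61% to 12.5% in Bif1;Bif4. The simulated genes varied independently of each other, unlike the genes of these libraries, so that the shares need not hold for the real calls. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.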

Results

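Maize tassels, the male inflorescences, were compared by RNA sequencing between wildtype plants and 2 mutants grown in the field in the B73 inbred background. The ndl1 (needle1) mutant carries a mutation in a gene labelled zmftsh10, a member of the FtsH family of membrane-bound ATP-dependent proteases. The series title places its product in mitochondria and links it to growth at high temperature. Bif1;Bif4 plants were heterozygous for mutations in both Bif1 and Bif4, and the affected genes encode Aux/IAA proteins, repressors of auxin signalling. Tassels of 2 to 4 mm were collected, a stage at which axillary meristems form on the flanks of the inflorescence. The labels state that the ndl1 samples included severely affected tassels that still formed a few axillary meristems. The 9 libraries comprised 3 of wildtype, 4 of ndl1 and 2 of Bif1;Bif4, with 16863087 to 22533736 reads counted to genes per library. The 10 genes with the most reads took 2.48% to 3.08% of the reads of a library. In a principal component analysis of the 9 libraries, the first component took 42.3% of the variance and the second 19.7%. On the first component the ndl1 libraries lay at 63.8, -2.47, 29.7 and 93.9 for replicates 1 to 4, the wildtype libraries at -62.4, -58.4 and -21.4 and the Bif1;Bif4 libraries at -22.8 and -19.9. The ndl1 library nearest to wildtype was replicate 2. On the second component both Bif1;Bif4 libraries, at 55.4 and 67.7, lay apart from the rest.

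Transcripts of the mutated genes were examined first. NDL1 (GRMZM2G038401) stood at 3209 ± 259 normalized counts in ndl1 (SD, n = 4) and 3325 ± 173 in wildtype (SD, n = 3), a log2 fold change of -0.05 ± 0.08 (SE, limma, Benjamini-Hochberg adjusted p = 0.743, groups overlapping). BIF1, listed as AUX22 (GRMZM2G130953), stood at 295 ± 221 in Bif1;Bif4 (SD, n = 2) and 372 ± 124 in wildtype (SD, n = 3), a log2 fold change of -0.51 ± 0.50 (limma, Benjamini-Hochberg adjusted p = 0.589, groups overlapping). BIF4 (GRMZM5G864847) stood at 156 ± 71.8 against 219 ± 59.1, a log2 fold change of -0.52 ± 0.34 (limma, Benjamini-Hochberg adjusted p = 0.406, groups overlapping). None of the 3 genes passed the test in its own mutant, and transcript amount therefore does not check the genotype labels. In the other mutant the log2 fold changes were -0.10 ± 0.08 for NDL1 in Bif1;Bif4, and -0.16 ± 0.25 for BIF1 and -0.84 ± 0.29 for BIF4 in ndl1, none of which passed.

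The comparison of ndl1 with wildtype asks which transcripts differ in tassels of the ndl1 mutant. The alternative oxidase gene Aox (GRMZM2G125669), whose product is a terminal oxidase of mitochondria that bypasses part of the proton-pumping respiratory chain, stood at 660.1 ± 231 normalized counts in ndl1 (SD, n = 4) and 1.67 ± 1.07 in wildtype (SD, n = 3). The glutathione transferase genes gst2 (GRMZM2G132093) and gst42 (GRMZM2G025190), whose products conjugate glutathione to reactive compounds, stood at 453 ± 63.3 against 3.03 ± 1.58 and at 775 ± 303 against 7.98 ± 4.10. Lower in ndl1 was barren stalk1 (BA1, GRMZM2G397518), a bHLH regulator of axillary meristem initiation, at 98.9 ± 59.1 against 324 ± 71.8. Also lower was barren stalk fastigiate1 (baf1, GRMZM2G072274), an AT-hook protein gene needed for the same step in ear shoots, at 93.4 ± 38.7 against 296 ± 42.9.

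The 10 largest rises among genes with a descriptive name had log2 fold changes from 3.23 to 7.96, with limma Benjamini-Hochberg adjusted p values from 2.96e-05 to 0.0449. All 4 ndl1 libraries lay above all 3 wildtype libraries for each of them, as the naming rule required. Aox led with 7.96 ± 0.34 (SE), followed by gst2 with 6.87 ± 0.27 and gst42 with 6.45 ± 0.36. The hemoglobin gene GLB1 (GRMZM2G067402) rose by 4.41 ± 0.47, the NAC transcription factor gene ANAC010 by 4.31 ± 0.56, and the TIFY family gene TIFY2 by 4.22 ± 0.89. PIN10a, a gene of the PIN family of auxin efflux carriers, rose by 4.12 ± 0.60, and NAC12 (GRMZM2G018436) by 3.73 ± 0.42. The series ended with gst20, which rose by 3.51 ± 0.66, and ppdk1 (GRMZM2G306345), the gene of pyruvate, phosphate dikinase, which rose by 3.23 ± 0.46. TIFY2 passed with limma and missed the threshold in edgeR (Benjamini-Hochberg adjusted p = 0.0553). For ppdk1 the authors' deposited table held no adjusted p in ndl1, while edgeR called it (Benjamini-Hochberg adjusted p = 0.0224). Its level was 1198 normalized counts in ndl1 replicate 4, against 349 to 467 in the other ndl1 libraries.

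Of 14 tested members of the list of mitochondrial stress and protease genes, 3 rose, none fell and 11 did not pass, and the same count of 3 was obtained when adjusted over the list alone. Beside Aox these were the prohibitin genes phb2 (0.72 ± 0.10) and phb3 (1.08 ± 0.18), with all 4 ndl1 libraries above wildtype. Prohibitins are scaffold proteins of the inner mitochondrial membrane that bind FtsH proteases. The list as a whole was shifted upwards (camera, Benjamini-Hochberg adjusted p = 0.00886, median log2 fold change 0.17, 9 of 14 members positive), with adjusted p = 0.246 with an estimated correlation and 0.0659 with ranks. Among 37 genes of oxidative stress and detoxification, 5 rose and none fell, and 7 rose when adjusted over the list alone. They were Aox, gst2, gst42, gst20 and gst41 (0.92 ± 0.10), so that Aox counts in both lists. This list was shifted upwards (camera, Benjamini-Hochberg adjusted p = 4.45e-05, median 0.22, 28 of 37 members positive), with adjusted p = 0.282 with an estimated correlation. The single testable member of the respiratory chain list, the ATP synthase subunit gene ATP2, had a log2 fold change of 0.03 ± 0.07 and did not pass.

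Genes of stress hormones and defence were shifted upwards, with 8 of 111 tested members rising and none falling, and 17 rising and 6 falling when adjusted over the list alone. The risers included the NAC genes ANAC010, NAC12 and NAC20 (3.19 ± 0.64), the WRKY gene WRKY30 (3.09 ± 0.52), and the ethylene-responsive element binding genes EREB94 (1.21 ± 0.15) and EREB179 (3.71 ± 0.60), with all 4 ndl1 libraries above wildtype. The list test gave camera, Benjamini-Hochberg adjusted p = 3.01e-05 (median 0.47, 80 of 111 positive), and adjusted p = 0.406 with an estimated correlation. Markers of vascular tissue and secondary walls, included as a sign of stem and rachis tissue, were also shifted upwards. Of 10 members 1 rose, the cinnamoyl-CoA reductase gene ccr2 (1.36 ± 0.29), and 3 rising when adjusted over the list alone. Their test gave camera, Benjamini-Hochberg adjusted p = 0.000772 (median 0.69, 10 of 10 positive), and adjusted p = 0.282 with an estimated correlation. The call of ccr2 missed the threshold in edgeR (Benjamini-Hochberg adjusted p = 0.0535). Both lists varied between libraries of a group. The mean log2 deviation from the wildtype mean was 0.19 for vascular genes and 0.17 for stress genes in ndl1 replicate 2, below 0.30 and 0.37 in wildtype replicate 3. The other ndl1 libraries lay from 0.86 to 1.07 and from 0.76 to 1.40.

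Regulators of inflorescence architecture were shifted downwards in ndl1. Of 62 tested members 4 fell, none rose and 58 did not pass, and 13 fell and 1 rose when adjusted over the list alone. BA1 fell by 1.83 ± 0.37 and baf1 fell by 1.73 ± 0.29 on the log2 scale. Thick tassel dwarf1 (TD1, listed as KIN5), a receptor kinase gene that limits meristem size, fell by 1.56 ± 0.25 and the WUSCHEL-related homeobox gene wox3A (listed as HB82) fell by 1.26 ± 0.24, with all 4 ndl1 libraries below wildtype. Limma Benjamini-Hochberg adjusted p values were 0.0396 for BA1, 0.0211 for baf1, 0.0190 for TD1 and 0.0330 for wox3A. BA1 missed the threshold in edgeR (Benjamini-Hochberg adjusted p = 0.0563). The list test gave camera, Benjamini-Hochberg adjusted p = 0.000559 (median -0.24, 44 of 62 negative), and adjusted p = 0.246 with an estimated correlation. The vascular and secondary wall markers lay higher in the same comparison (median log2 fold change 0.69, 10 of 10 members positive). Of the 36 tested members of this list and the auxin list that were given by symbol, 3 fell (BA1, baf1 and TD1) and 33 did not pass. The 33 had log2 fold changes from -2.12 to 1.60, of which 29 were negative, and the lowest limma Benjamini-Hochberg adjusted p among them was 0.0758. They included the branching regulators ra1 (-2.08 ± 0.73) and ra3 (-1.66 ± 0.45), the meristem homeobox genes kn1 (-0.37 ± 0.14) and wus1 (-1.14 ± 0.29), the kinase gene bif2 (-0.63 ± 0.26), and the auxin biosynthesis gene spi1 (-0.74 ± 0.22). The authors' deposited table called ra1 and ra3 lower in ndl1 (DESeq2, Benjamini-Hochberg adjusted p = 0.0362 and 0.0397). By edgeR neither was called (Benjamini-Hochberg adjusted p = 0.134 and 0.0873). Values close to 0 were found for the meristem size genes fea2 (-0.09 ± 0.13) and ct2 (-0.03 ± 0.08), and ts1, a lipoxygenase gene of sex determination, was at 1.60 ± 0.57.

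The floral MADS box list was planned as a sign of later spikelets but took MADS box genes of any kind by name. It was likewise lower, with 4 of 18 members falling and none rising, and 5 falling and 1 rising when adjusted over the list alone. MADS36 fell by 1.69 ± 0.24, from 4078 ± 331 normalized counts in wildtype to 1312 ± 434 in ndl1. ZAGL1 fell by 0.73 ± 0.11, m5 fell by 1.08 ± 0.20 and m16 fell by 0.70 ± 0.14, each in all 4 libraries. The list test gave camera, Benjamini-Hochberg adjusted p = 0.00713 (median -0.24, 14 of 18 negative), and adjusted p = 0.406 with an estimated correlation. Beside the falls of this list and of the cell cycle list, vascular markers again had a median of 0.69. For ndl1 replicates 1 to 4 the mean log2 deviation from wildtype was 1.07, 0.19, 0.86 and 0.93 for vascular markers. For the floral MADS box list it was -0.64, -0.44, -0.33 and -0.55. Replicate 2 was thus lowest for vascular markers without the smallest fall of the MADS box list. In these bulk samples fewer cells of a kind and lower transcript levels per cell cannot be told apart. The remaining genes among the 10 largest falls were the cytochrome P450 gene CYP78A53 (-1.74 ± 0.36), the ovate family gene OFP28 (-1.57 ± 0.19), the homeobox gene HB21 (-1.54 ± 0.30), the boundary NAC gene nam1 (listed as CUC2, -1.39 ± 0.23) and BT2A (-1.32 ± 0.22). Limma Benjamini-Hochberg adjusted p values of the 10 ran from 0.00646 to 0.0427, with all 4 ndl1 libraries below wildtype. Cell cycle genes were shifted downwards as a list without any of the 30 members passing limma. Of these, 7 reached an unadjusted p under 0.05, 0 passed in edgeR and 2 in DESeq2. Their test gave camera, Benjamini-Hochberg adjusted p = 0.00713 (median -0.13, 23 of 30 negative, 0 passing when adjusted over the list alone), and adjusted p = 0.558 with an estimated correlation. Without ndl1 replicate 1 the cell cycle shift no longer passed (camera, Benjamini-Hochberg adjusted p = 0.0901, downward).

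Another 6 lists did not pass as a whole in ndl1. Of 46 auxin pathway genes 5 rose and 2 fell, and 6 rose and 6 fell when adjusted over the list alone. The risers were PIN10a, the auxin-conjugating enzyme gene GH3 (1.52 ± 0.22), AUX3 (1.05 ± 0.19) and the auxin response factor genes ARF9 (0.60 ± 0.11) and ARF3 (0.69 ± 0.14). The genes that fell were BA1 and baf1. This list had a median of -0.01 and a mean of 0.02, opposite in sign, and its test pointed downwards (camera, Benjamini-Hochberg adjusted p = 0.954, 24 of 46 negative). Of 8 anther and meiosis genes, the cohesin gene afd1 (1.14 ± 0.11) and the recombinase gene Dmc1 (1.24 ± 0.21) rose and the synaptonemal complex gene ZYP1 fell (-0.50 ± 0.10). In this list 3 rose and 2 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.254, median 0.12, 6 of 8 positive). Of 31 heat shock and chaperone genes 1 rose, the heat shock factor gene HSF6 (1.06 ± 0.20), also the single riser when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.345, median -0.13, 22 of 31 negative). Of 8 photosynthesis genes ppdk1 rose, and 1 rose and 1 fell when adjusted over the list alone. The list had a median of -0.37, a mean of 0.15 and a downward test (camera, Benjamini-Hochberg adjusted p = 0.540, 6 of 8 negative). No member passed limma, nor edgeR or DESeq2, among 34 ribosomal protein genes (1 at an unadjusted p under 0.05; camera, Benjamini-Hochberg adjusted p = 0.553, median -0.01, 18 of 34 negative). The same held for 11 histone genes (0 at an unadjusted p under 0.05; camera, Benjamini-Hochberg adjusted p = 0.0555, median -0.24, 10 of 11 negative), with 0 members of either list passing when adjusted over the list alone. Without ndl1 replicate 3, whose histone mean lay at 0.32 against -0.77 to -0.26 in the other ndl1 libraries, the histone list passed downwards (camera, Benjamini-Hochberg adjusted p = 0.000143), and with all libraries it passed downwards when ranks were used (adjusted p = 0.0269). With an estimated correlation it had adjusted p = 0.714 over all libraries (camera, Benjamini-Hochberg).

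Over all 22416 genes tested, 708 differed between ndl1 and wildtype by limma, 434 higher and 274 lower in ndl1. At an adjusted p of 0.01 limma called 114 higher and 24 lower. Of all genes tested, 20.1% had no overlap between the 4 ndl1 and the 3 wildtype libraries, which chance gives in 5.71%. All 708 called genes had no overlap, so that a lack of overlap adds nothing to a call. On the recovered reads edgeR called 684 genes, 659 of them among the 708 in the same direction. DESeq2 called 2228, with 707 of the 708 among them, and the authors' deposited table held 2030. The count was 238, 111 and 340 without wildtype replicates 1, 2 and 3, and 265, 1467, 587 and 554 without ndl1 replicates 1, 2, 3 and 4, so that it depended on single libraries of both groups. Genes called lower numbered 62, 15 and 72 without wildtype replicates 1, 2 and 3, against 274 with all libraries. Genes called higher numbered 176, 96 and 268, against 434. Without ndl1 replicates 1, 2, 3 and 4 the lower genes numbered 86, 421, 257 and 216, and the higher genes 179, 1046, 330 and 338. Of 38 named genes called with all libraries, 12 were still called without wildtype replicate 2 and 37 without ndl1 replicate 2.

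**Figure D1:**
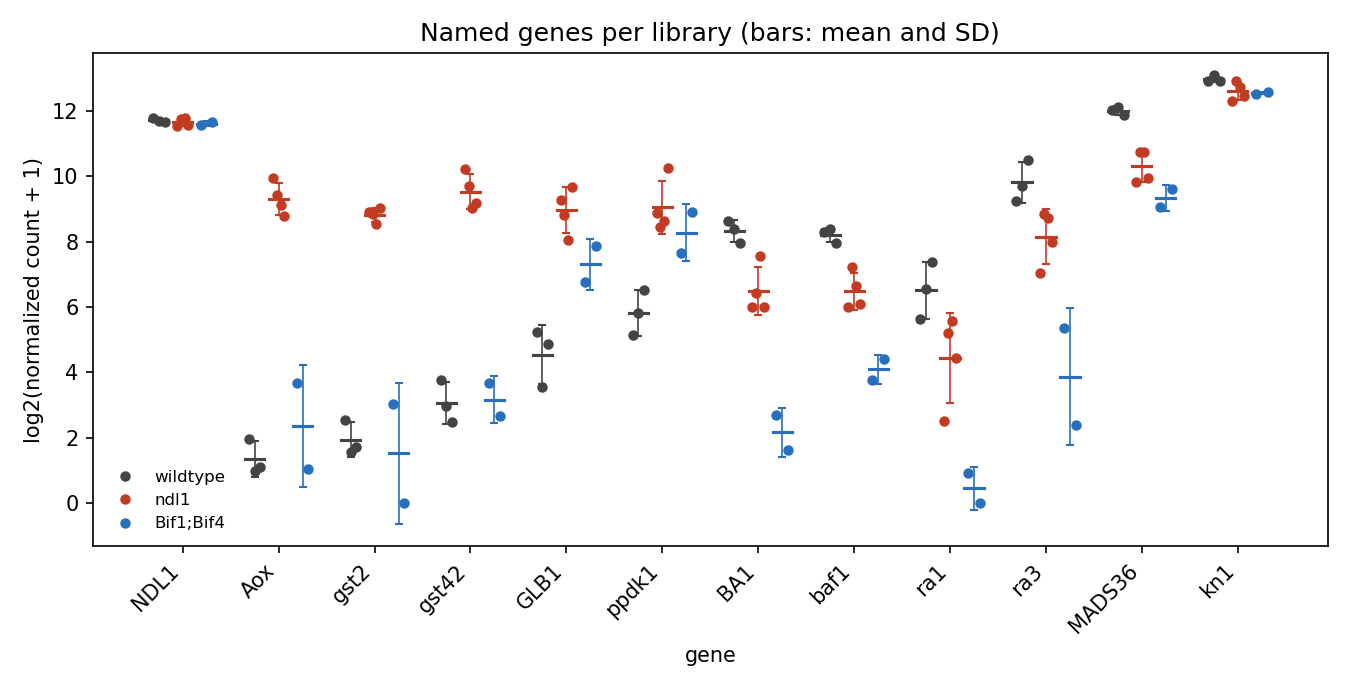
Named genes in the 9 libraries scaled together, with the gene on the horizontal axis and log2(normalized count + 1) on the vertical axis; points are libraries (3 wildtype, 4 ndl1, 2 Bif1;Bif4), horizontal lines group means and vertical lines SD. Aox, gst2 and gst42 stand higher in all 4 ndl1 libraries than in any other library, BA1, baf1, ra1 and ra3 are lowest in the 2 Bif1;Bif4 libraries, and NDL1 lies at a similar level in all 9.

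The comparison of Bif1;Bif4 with wildtype asks which transcripts differ in tassels with altered Aux/IAA repressors. BA1 stood at 3.75 ± 2.33 normalized counts in Bif1;Bif4 (SD, n = 2) and 321 ± 72.7 in wildtype (SD, n = 3), and baf1 at 16.2 ± 5.23 against 293 ± 43.6. The ramosa genes ra1 and ra3, which control branching of the tassel, were also lower. The trehalose phosphatase gene ra3 (GRMZM2G014729) stood at 21.8 ± 24.8 against 945 ± 423. The zinc finger gene ra1 (GRMZM2G003927) had 1 read in the 2 Bif1;Bif4 libraries against 286 in the 3 wildtype libraries, a 200.8-fold lower level with a 95% counting interval of 35.8 to 7959 (exact binomial, counting error only). Higher in Bif1;Bif4 were the terpene synthase gene TPS17 (listed as EDS, GRMZM2G010356) at 377 ± 189 against 32.2 ± 25.6, and the hemoglobin gene GLB1 at 166 ± 85.8 against 24.9 ± 13.2.

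The 10 largest falls among genes with a descriptive name were led by BA1 with a log2 fold change of -6.15 ± 0.37 (SE), ra1, ra3 (-5.94 ± 0.80) and the polyamine oxidase gene MPAO (-5.29 ± 0.71). They continued with the small heat shock gene hsp22 (-4.21 ± 0.70), baf1 (-4.12 ± 0.25), OFP28 (-3.94 ± 0.30), the branch angle gene BAD1 (-3.70 ± 0.31), a TCP family member, the ACC oxidase gene acco20 (-2.96 ± 0.39) and MADS36 (-2.68 ± 0.16). Limma Benjamini-Hochberg adjusted p values of these 10 ran from 0.00303 to 0.0294, with both Bif1;Bif4 libraries below all 3 wildtype libraries. Of these, ra3 and hsp22 were not called in the authors' deposited table (DESeq2, Benjamini-Hochberg adjusted p = 0.0798 and 0.0706). The 10 largest rises had smaller log2 fold changes, from 1.49 to 3.69, with limma Benjamini-Hochberg adjusted p values from 0.00457 to 0.0475 and both Bif1;Bif4 libraries above wildtype. They were TPS17 (3.69 ± 0.61), GLB1 (2.75 ± 0.56), ppdk1 (2.45 ± 0.48), ZCN2 (2.36 ± 0.40), a gene of the family of FT and TFL1, and the zinc finger gene Nkd2 (listed as IDD9, 1.70 ± 0.13). The others were BURP10 (1.66 ± 0.19), the prolyl hydroxylase gene P4H4 (1.63 ± 0.14), GRF9 (1.55 ± 0.25), the SBP box gene sbp2 (1.55 ± 0.31) and the MADS box gene tunicate1 (listed as m19, 1.49 ± 0.31).

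Of 64 tested inflorescence regulators 10 fell and 3 rose, and 25 fell and 6 rose when adjusted over the list alone. Beside BA1, baf1, ra1 and ra3, falls were found for TD1 (-1.40 ± 0.19), the liguleless genes lg1 (-1.16 ± 0.24) and lg2 (-1.25 ± 0.19), wox9C (-1.12 ± 0.20), wox3A (-1.65 ± 0.30) and the meristem homeobox gene kn1 (-0.42 ± 0.09). The genes that rose were sbp29 (0.80 ± 0.10), sbp2 and tunicate1. The list test gave camera, Benjamini-Hochberg adjusted p = 0.000279 (median -0.27, 44 of 64 negative), and adjusted p = 0.189 with an estimated correlation. Vascular and secondary wall markers lay higher in the same libraries (median log2 fold change 0.99, 11 of 11 members positive). Calls of kn1 and lg1 rested near the threshold, with both Bif1;Bif4 libraries below wildtype. Limma Benjamini-Hochberg adjusted p values were 0.0479 and 0.0470, and edgeR values were 0.0504 and 0.0528. Of the 37 members given by symbol 8 fell (BA1, baf1, ra1, ra3, TD1, kn1, lg1 and lg2). The other 29 did not pass, 19 of them negative, with a lowest limma Benjamini-Hochberg adjusted p of 0.0550. Among the 29, bd1 had no read in either Bif1;Bif4 library against 120 reads in wildtype, which put it at least 28.1-fold lower at a floor of 3 reads over the group. The other 28 ran from -2.22 to 1.05. They included the kinase gene bif2 (-1.20 ± 0.33), spi1 (-0.18 ± 0.17), ts2 (-1.57 ± 0.35), the SBP box genes ub2 (0.69 ± 0.22) and ub3 (1.05 ± 0.26), and fea3 (0.83 ± 0.19).

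Heat shock and chaperone genes were shifted downwards in Bif1;Bif4, with 6 of 31 falling and 1 rising, and 12 falling and 2 rising when adjusted over the list alone. The falls were hsp22, the endoplasmic reticulum chaperone genes bip1 (listed as b-70, -1.43 ± 0.21) and bip2 (-1.14 ± 0.20), HSP90-2 (-1.24 ± 0.21), and the mitochondrial chaperonin genes CPN60II (-0.82 ± 0.12) and CPN60I (GRMZM2G458208, -0.97 ± 0.20), and the heat shock factor gene HSF2 rose (0.68 ± 0.11). The test gave camera, Benjamini-Hochberg adjusted p = 3.94e-05 (median -0.82, 26 of 31 negative), and adjusted p = 0.326 with an estimated correlation. Single libraries spread widely in this list, with mean log2 deviations from wildtype of -0.59 and -1.26 in Bif1;Bif4 and 0.28 in wildtype replicate 2. The mitochondrial stress list was also shifted downwards, with 12 members tested here against 14 in ndl1. Aox had too few reads to be tested here, with a mean of 6.44 normalized counts in Bif1;Bif4 (9 libraries scaled together). The shifts of this list in the 2 mutants therefore rest on partly different members. Of the 12 tested members of the list the chaperonin genes CPN60I and CPN60II, which count in the heat shock list as well, fell and none rose. When adjusted over the list alone 3 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 0.0311, median -0.20, 9 of 12 negative). It had adjusted p = 0.329 with an estimated correlation, and without Bif1;Bif4 replicate 2 it no longer passed (camera, Benjamini-Hochberg adjusted p = 0.242, downward), nor with ranks (0.0522). The respiratory chain gene ATP2 had a log2 fold change of -0.01 ± 0.08 and did not pass.

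The ribosomal protein, histone, cell cycle and floral MADS box lists were shifted downwards. Beside these falls, and those of the heat shock and mitochondrial stress lists, vascular markers had a median of 0.99. Here too cell content and transcript levels per cell cannot be told apart in bulk samples. Of 34 ribosomal protein genes arpp2a-3 (-0.65 ± 0.08) and rps13 (-0.38 ± 0.07) fell and none rose, with 4 falling and 1 rising when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.43e-05, median -0.17, 30 of 34 negative; adjusted p = 0.411 with an estimated correlation). Of 11 histone genes his2b5 (-0.53 ± 0.08), H1 (-0.48 ± 0.10) and H4C13 (-0.48 ± 0.10) fell, with 7 falling when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000298, median -0.32, 10 of 11 negative; adjusted p = 0.326 with an estimated correlation). Of 30 cell cycle genes the kinase gene wee1 fell (-0.62 ± 0.09), with 4 falling when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00185, median -0.12, 22 of 30 negative; adjusted p = 0.326 with an estimated correlation). Of 21 floral MADS box genes 6 fell and 2 rose, and 10 fell and 5 rose when adjusted over the list alone. MADS36, m16 (-1.35 ± 0.15), ZAGL1 (-0.60 ± 0.08), MADS76 (-1.53 ± 0.28), m6 (-3.17 ± 0.60) and m5 (-0.54 ± 0.11) fell, and tunicate1 and m31 (0.55 ± 0.09) rose. That list passed (camera, Benjamini-Hochberg adjusted p = 0.0285, median -0.27, 13 of 21 negative), with adjusted p = 0.326 with an estimated correlation. It lost the call without wildtype replicate 1, 2 or 3 (camera, Benjamini-Hochberg adjusted p = 0.0974, 0.0641 and 0.0662, downward each time), with ranks (adjusted p = 0.114) and with a mean count filter of 10 (adjusted p = 0.117).

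Vascular and secondary wall markers were shifted upwards, with 1 of 11 rising, the cinnamoyl-CoA reductase gene CCR (1.04 ± 0.21), also the 1 riser when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00213, median 0.99, 11 of 11 positive; adjusted p = 0.326 with an estimated correlation). Library means of this list were 1.17 and 0.52 in Bif1;Bif4 and 0.30 in wildtype replicate 3. Among oxidative stress genes Aox and gst2 had too few reads to be tested here. Of the 32 tested gst6 rose (1.13 ± 0.18), and 2 rose and 1 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0130, median 0.27, 24 of 32 positive, and adjusted p = 0.420 with an estimated correlation). The call ended without Bif1;Bif4 replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.225, upward). Of 47 auxin pathway genes the response factor gene ARF13 rose (0.60 ± 0.10), while ARF11 (-0.73 ± 0.11), AUX10 (-2.38 ± 0.38), BA1 and baf1 fell, and 14 rose and 6 fell when adjusted over the list alone. The list test nevertheless pointed upwards (camera, Benjamini-Hochberg adjusted p = 0.0351, median 0.27, 30 of 47 positive), with adjusted p = 0.326 with an estimated correlation. It ended without wildtype replicate 1 or Bif1;Bif4 replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.124 and 0.188, upward both times) and with a mean count filter of 10 (adjusted p = 0.0559).

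In Bif1;Bif4 3 lists did not pass. Of 101 stress hormone and defence genes 5 rose and 3 fell, and 7 rose and 3 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.242, median 0.10, 61 of 101 positive). The risers included EREB161 (0.77 ± 0.07), the lipoxygenase gene lox11 (1.20 ± 0.14) and EREB179 (3.41 ± 0.54), and acco20, EREB85 (-1.05 ± 0.19) and EREB93 (-1.80 ± 0.36) fell. Without wildtype replicate 3, where this list stood at 0.37 above the wildtype mean, it passed upwards (camera, Benjamini-Hochberg adjusted p = 0.00270). With all libraries and an estimated correlation it had adjusted p = 0.747 (camera, Benjamini-Hochberg). Of 9 photosynthesis genes ppdk1 rose, and 1 rose and 1 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.546, median 0.05, 6 of 9 positive). Its library means were 1.12 and -0.12 in Bif1;Bif4 and 0.49 in wildtype replicate 3, and without Bif1;Bif4 replicate 2 it passed upwards (camera, Benjamini-Hochberg adjusted p = 0.00471). With all libraries and an estimated correlation the photosynthesis list had adjusted p = 0.747 (camera, Benjamini-Hochberg). Of 8 anther and meiosis genes afd1 rose (0.44 ± 0.08), the single call also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.728, median 0.04, 5 of 8 positive).

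Over 22381 genes tested, 957 differed between Bif1;Bif4 and wildtype by limma, 498 higher and 459 lower in the mutant. At an adjusted p of 0.01 limma called 37 higher and 51 lower. Of all genes tested, 42.1% had no overlap between the groups, which chance gives in 20%. All 957 called genes had no overlap, which therefore adds nothing to a call. On the recovered reads edgeR called 944 genes, 914 of them among the 957 in the same direction. DESeq2 called 2055, with 952 of the 957 among them, and the authors' deposited table held 2028. The count rested on single libraries of both groups. It was 492 and 1 without wildtype replicates 1 and 2, 48 and 29 without Bif1;Bif4 replicates 1 and 2, and 1299 without wildtype replicate 3. Of 48 named genes called with all libraries, 33 were still called without wildtype replicate 1, 45 without wildtype replicate 3, and 6 and 5 without Bif1;Bif4 replicates 1 and 2. Without wildtype replicate 2 limma called 0 of the 48, against 48 at an unadjusted p under 0.05, 0 by edgeR and 46 by DESeq2.

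**Figure D2:**
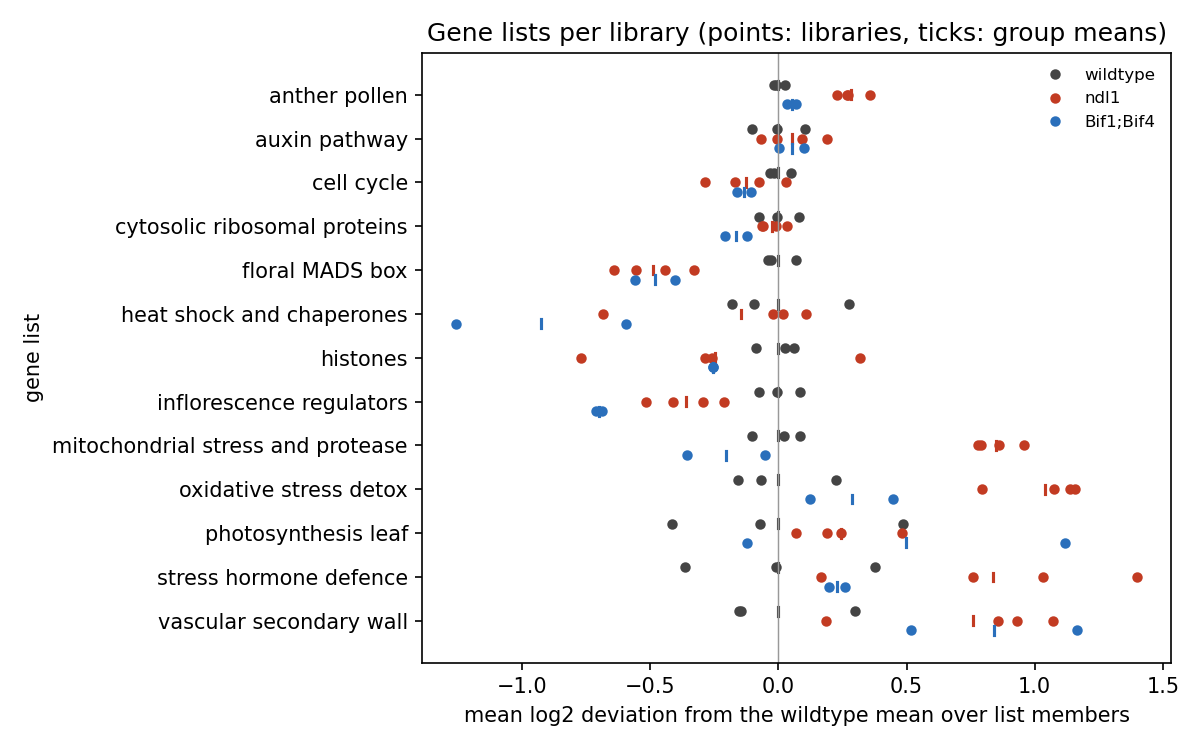
Gene lists per library, with the list on the vertical axis and the mean log2 deviation from the wildtype mean over list members on the horizontal axis; points are libraries (3 wildtype, 4 ndl1, 2 Bif1;Bif4) and ticks are group means. Inflorescence regulators lie below 0 in all 4 ndl1 libraries and both Bif1;Bif4 libraries, and the heat shock list lies at -0.59 and -1.26 in Bif1;Bif4, with -0.68 in ndl1 replicate 4.

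Both mutants were compared with the same wildtype libraries, which asks how far the changes coincide. BA1, baf1, TD1, wox3A, MADS36 and OFP28 fell in both, and GLB1, ppdk1, BURP10 and EREB179 rose in both. BURP10 rose by 2.74 ± 0.16 in ndl1 and 1.66 ± 0.19 in Bif1;Bif4, and OFP28 had log2 fold changes of -1.57 ± 0.19 and -3.94 ± 0.30. In a direct comparison of the mutants, with the 9 libraries scaled together, Aox was higher in ndl1 by 6.95 ± 0.65, gst2 by 7.30 ± 0.68 and gst42 by 6.36 ± 0.45 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.000705, 0.000705 and 0.000224, 4 of 4 ndl1 libraries above both Bif1;Bif4 libraries). BA1 was higher in ndl1 than in Bif1;Bif4 by 4.33 ± 0.46, baf1 by 2.39 ± 0.34, ra3 by 4.28 ± 0.77 and OFP28 by 2.36 ± 0.28 (limma, Benjamini-Hochberg adjusted p = 0.00144, 0.00638, 0.0179 and 0.00234, 4 of 4 ndl1 libraries higher). A difference between the mutants was not called for GLB1 (1.65 ± 0.55), PIN10a (0.68 ± 0.87), MADS36 (0.98 ± 0.27), TD1 (-0.16 ± 0.28) or kn1 (0.04 ± 0.15), with limma Benjamini-Hochberg adjusted p values of 0.157, 0.732, 0.0966, 0.802 and 0.915. Over all 23203 genes tested this way, 806 differed, 416 higher and 390 lower in ndl1. They held 206 of the 532 genes called in ndl1 and not in Bif1;Bif4. Of the 434 genes called higher in ndl1, 365 were tested in both comparisons, so that some of the 532 were never tested in Bif1;Bif4.

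Of 22056 genes tested in both comparisons, 80 were called higher in both mutants, 80 lower in both and 16 in opposite directions. Independent lists of these sizes would share 7.71 higher and 5.65 lower genes. The shared genes split into 19 higher and 16 lower without wildtype replicate 1, and into 65 and 31 without wildtype replicate 3. In 20 simulated pairs of unchanged mutants against the same wildtype libraries at most 3 and 5 genes were called per mutant, too few for a shared count to be set beside the observed one. The covariance of the log2 fold changes across genes was 0.147, against a mean of 0.0436 in those 20 pairs, a difference of 0.103. In 100 pairs that kept the correlation between genes, drawn from the deviations within all 3 groups, the mean was 0.0520, a difference of 0.0946. Of these 100 pairs 12 reached the observed value, with a highest of 0.269. The correlation across genes, which are not independent replicates, was 0.509, against a mean of 0.492 and a highest of 0.520 in the 20 pairs. With 3 wildtype libraries the controls could not be split between the comparisons, and part or all of the excess may come from the shared controls. The 160 genes called in the same direction numbered 35, 0 and 96 without wildtype replicates 1, 2 and 3, 70 and 231 without ndl1 replicates 1 and 2 (127 and 134 without replicates 3 and 4), and 20 and 18 without Bif1;Bif4 replicates 1 and 2. Without wildtype replicate 2 the 0 of limma stood beside 995 genes at an unadjusted p under 0.05 in both, 0 genes by edgeR and 156 by DESeq2.

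Among the 16 genes called in opposite directions, GRMZM2G068091 had no read in any of the 4 ndl1 libraries against 410 reads in wildtype, at least 192-fold lower at a floor of 3 reads over the group, and rose by 1.28 ± 0.19 in Bif1;Bif4. GRMZM2G114882 stood at 1.60 ± 2.09 normalized counts in ndl1 and 155 ± 20.2 in wildtype, a log2 fold change of -6.28 ± 0.62, and rose by 1.05 ± 0.15 in Bif1;Bif4. This gene lies among the 100 tested genes on each side of NDL1. GRMZM2G050625 went the other way, with 0.79 ± 0.10 in ndl1 and -3.77 ± 0.21 in Bif1;Bif4. The direct comparison called all 3 (limma, Benjamini-Hochberg adjusted p = 1.46e-06, 0.000557 and 1.46e-06), with the 4 ndl1 libraries on one side of both Bif1;Bif4 libraries. These calls follow largely from choosing genes with opposite changes in the same libraries and are no separate evidence. None of these identifiers has a descriptive name in the reference used.

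**Figure D3:**
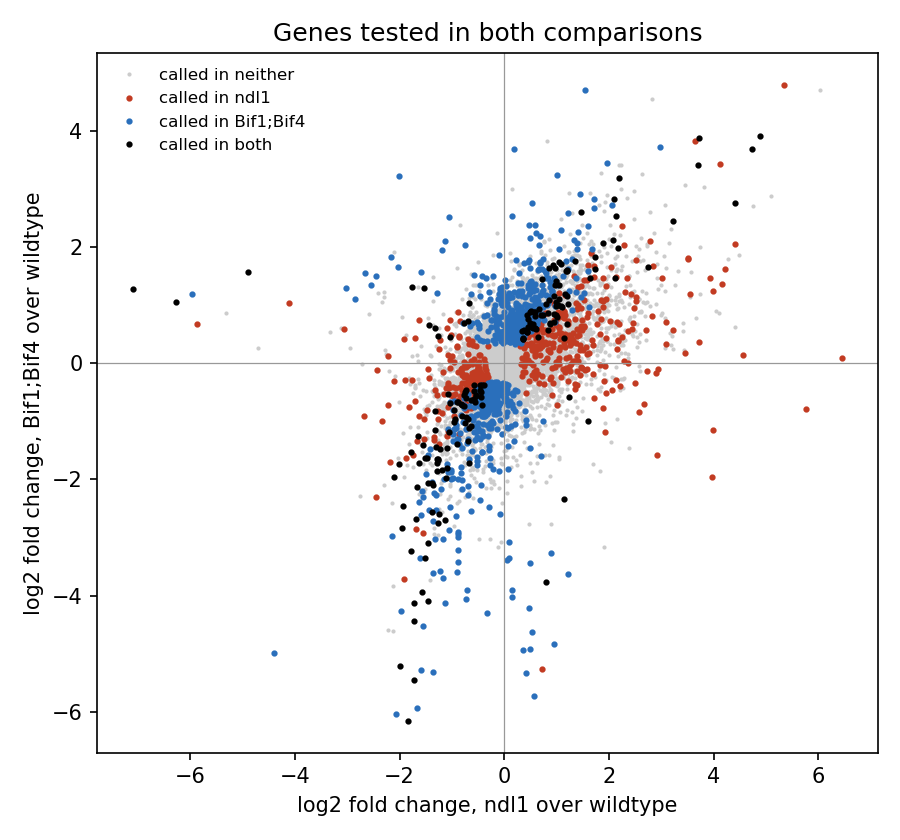
Genes tested in both comparisons, with the log2 fold change of ndl1 over wildtype on the horizontal axis and of Bif1;Bif4 over wildtype on the vertical axis; each point is a gene, black where called in both, red in ndl1, blue in Bif1;Bif4 and grey in neither. The black points hold 80 genes higher in both, 80 lower in both and 16 in opposite directions.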

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

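In each of 86 groups of 4 values from the ndl1 libraries, the distance of an extreme library from the nearest other was compared with the range of the group (Dixon's test), a planned test, and 4 groups passed, where chance passes about 1 in 20. BIF1 (AUX22) stood at 448 normalized counts in ndl1 replicate 3, against 282 to 291 in the other ndl1 libraries. The ppdk1 gene (C4ppdkZm1) stood at 1198 in ndl1 replicate 4, against 349 to 467 in the others. The kinase gene bif2 stood at 42.7 in ndl1 replicate 1, against 75.8 to 80.0 in the others. The mean log2 deviation of the heat shock and chaperone list was -0.68 in ndl1 replicate 4, against -0.02 to 0.11 in the others. No explanation was tested for these 4 values.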

How the results depend on the processing

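The alternatives chosen only after the data were seen were the authors' deposited adjusted p, the overlap by edgeR, DESeq2 and the authors' table and without each library, and the direct comparison of the mutants; the others were planned. The cause was not tested for any difference given here, except that stricter thresholds leave fewer calls by construction. The 708 genes of ndl1 became 2228 with DESeq2, 1809 with the authors' p-values adjusted over all genes, 2030 in the authors' deposited table, 138 at adjusted p 0.01 and 392 with an absolute log2 fold change of at least 1. The 957 genes of Bif1;Bif4 became 2055, 1829, 2028, 88 and 418 in the same order. The 160 genes shared in direction became 588 with DESeq2, 568 in the authors' table, 5 at adjusted p 0.01 and 71 with the fold change minimum, and 156 with edgeR. In the other settings, apart from the replicate block, counts stayed within 1.5 times, from 656 without a filter to 1047 with all groups in 1 fit for ndl1 and from 639 with all groups in 1 fit to 980 with a pseudocount of 4 for Bif1;Bif4. Leaving out single libraries gave 111 (without wildtype replicate 2) to 1467 (without ndl1 replicate 2) genes for ndl1, 1 (without wildtype replicate 2) to 1299 (without wildtype replicate 3) for Bif1;Bif4 and 0 (without wildtype replicate 2) to 231 (without ndl1 replicate 2) for the overlap; beside the 0 by limma stood 995 at an unadjusted p under 0.05, 0 by edgeR and 156 by DESeq2. At the depth and library number of these data limma recovered 58.6% (ndl1) and 60.4% (Bif1;Bif4) of simulated 2-fold changes, with genes drawn independently of each other. Where a single Bif1;Bif4 library was left, it was assumed to vary like the wildtype libraries. Lists passing numbered 7 in ndl1 and 10 in Bif1;Bif4, 6 to 8 and 8 to 10 without single libraries, and 0 in both with an estimated correlation (2 and 1 at an unadjusted p under 0.05 by camera).

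Same-numbered libraries did not deviate together: correlations of deviations were -0.107, 0.217 and -0.00751 for ndl1 with wildtype replicates 1, 2 and 3, and -0.217 and -0.172 for Bif1;Bif4 replicates 1 and 2, and not every library correlated best with its own number. With the replicate block 413 genes were called in ndl1 and 585 in Bif1;Bif4, and of the named genes called without it 28 of 38 and 32 of 48 were called. In Bif1;Bif4 the list of stress hormones and defence passed upwards (camera, Benjamini-Hochberg adjusted p = 0.00118; without the block, adjusted p = 0.747 with an estimated correlation) and the floral MADS box list did not pass (adjusted p = 0.0740, downward), and no list call changed in ndl1. The block also takes ndl1 replicate 4 and wildtype replicate 3, which have no partner of their number, out of the estimates in ndl1 and Bif1;Bif4; leaving out these libraries without a block gave 554 and 1299 genes and the same fold changes of lg1 and M14. With the block lg1 in ndl1 turned to 0.0248, the heat shock list in ndl1 turned upward (camera on limma values, unadjusted p = 0.863) and M14 in Bif1;Bif4 turned to -0.35. Splitting the controls between the comparisons was not run, since 3 wildtype libraries do not leave 2 in each part.

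Among the named genes and the lists, sign changes were confined to those not called. In ndl1 ids1 turned positive with DESeq2 (0.00123), edgeR with TMM (0.00274) or size factors (0.00420) and in the authors' table (0.00113). In Bif1;Bif4 M14 turned negative with DESeq2 (-1.62), edgeR with TMM or size factors (-1.59 in both) and a pseudocount of 4 (-0.18). Without single libraries the log2 fold changes in ndl1 ran from -0.30 to 0.20 for wus2 (HB122), -0.44 to 0.0611 for BIF1 (AUX22), -0.0394 to 0.34 for ub2, -0.11 to 0.0942 for ids1, -0.0914 to 0.0423 for ct2 and -0.63 to 0.0248 for lg1. In Bif1;Bif4 they ran from -0.14 to 0.00125 for rel2, -0.0825 to 0.12 for ct2, -0.88 to 1.30 for M14, -0.29 to 0.72 for ts1, -1.36 to 0.34 for BIF1 (AUX22), -1.41 to 0.00602 for wus1 and -0.76 to 0.0603 for EREB121. Unadjusted camera p values of lists that turned ran in ndl1 from 0.0392 to 0.820 for ribosomal proteins, 0.531 to 0.981 for auxin, 0.293 to 0.704 for photosynthesis and 0.0647 to 0.954 for heat shock, and in Bif1;Bif4 from 0.00166 to 0.571 for stress and 0.00290 to 0.720 for photosynthesis. Over all settings, single-gene results kept direction and side of the threshold in 1331 cases in ndl1 and 1160 in Bif1;Bif4, lost the call in 145 and 259, gained it in 14 and 40 and turned in 18 and 16.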

Other observations

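The tests of called genes among the neighbours of NDL1, BIF1 and BIF4, the bound for genes of unknown order, and the comparison of the covariance with simulated pairs that keep the correlation between genes, were chosen only after the result was seen, as were the glycolytic and protein folding genes named here.

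The enolase gene eno1 (GRMZM2G064302) stood at 24145 ± 1905 normalized counts in ndl1 and 11105 ± 422 in wildtype (log2 fold change 1.12 ± 0.09), and the aldolase gene ald1 (1.15 ± 0.13), the glyceraldehyde phosphate dehydrogenase gene gpc4 (1.19 ± 0.14) and the triosephosphate isomerase gene TIM (0.61 ± 0.09) rose as well. No list of glycolytic genes was tested. Limma Benjamini-Hochberg adjusted p values were 0.000929, 0.00445, 0.00574 and 0.0118, with 4 of 4 ndl1 libraries above wildtype. The second enolase gene eno2 had a log2 fold change of -0.01 ± 0.11 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.958, groups overlapping). In Bif1;Bif4 eno1 (-0.09 ± 0.08), ald1 (0.50 ± 0.12) and gpc4 (-0.08 ± 0.13) did not pass. Values of TIM in Bif1;Bif4 and between the mutants are not reported here. In the direct comparison of the mutants eno1 was higher in ndl1 by 1.21 ± 0.10, ald1 by 0.65 ± 0.14 and gpc4 by 1.26 ± 0.16 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.000404, 0.0343 and 0.00361, 4 of 4 ndl1 libraries above both Bif1;Bif4 libraries). The alcohol dehydrogenase gene adh1 rose in both mutants, by 0.88 ± 0.17 in ndl1 and 0.69 ± 0.14 in Bif1;Bif4 (limma, Benjamini-Hochberg adjusted p = 0.0323 and 0.0470, all mutant libraries above wildtype).

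In Bif1;Bif4 the calnexin gene CNX (GRMZM2G022180) had a log2 fold change of -0.79 ± 0.09 and the disulfide isomerase gene pdi2 of -0.54 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.0130 and 0.0203, 2 of 2 libraries below wildtype). A second disulfide isomerase gene, pdi, stood at -0.01 ± 0.09 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.974, groups overlapping), and no list of such genes was tested.

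The count of 708 genes between ndl1 and wildtype was compared with all splits of the 7 libraries into 4 and 3. Of 35 splits 1, the real one, gave as many genes, which argues against chance as its source. The highest other count was 450, for the 3 wildtype libraries with ndl1 replicate 2 against the other ndl1 libraries. That split points to a structure of the samples in which ndl1 replicate 2 lies near wildtype, and without this library 1467 genes were called. Whether it comes from a milder phenotype or from handling was not tested.

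Fold changes of both mutants went together across genes, with a covariance of 0.147. The 100 simulated pairs of unchanged mutants with shared wildtype libraries and correlated genes had a mean of 0.0520 and a highest value of 0.269, and 12 of them reached the observed value. In the 20 simulated pairs with independent genes, which were run first, the highest value was 0.0468, and the observed value lay above the bound set for that test. That bound left out that genes vary together in these libraries, and the correlated pairs spread as far as 0.269. Those pairs mixed the deviations within all 3 groups. On the first component the ndl1 libraries spread more widely (-2.47 to 93.9) than the wildtype libraries (-62.4 to -21.4). The 0.269 may therefore overstate what the wildtype libraries alone would give, and neither set of pairs was matched to their spread. Shared wildtype libraries and an effect common to both mutants therefore cannot be told apart here.

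Genes with a mean under 3 normalized counts in one genotype and at least 20 in the other numbered 35 in ndl1 and 41 in Bif1;Bif4, limits set before the neighbour test was computed but after the means of named genes had been seen. Among the 100 tested genes on each side lay 1 of 20 genes with a known order for NDL1, or 5%, and 0 of 12 for BIF1 and BIF4, or 0%, and of the genes near zero in ndl1 itself 1 of the 2 with a known order lay there, but with an order known for 57.1% and 29.3% of the 35 and 41 genes, under the 80% needed, the check on those shares is void. In ndl1 19 of the 35 lay outside the window, so that at most 16, or 45.7%, could lie in it. That argues against a segment within this window as the source of most of the 35 as a set and leaves it open for those 16. A segment reaching beyond the window was not tested. Only 5 of the 35 were near zero in ndl1 itself, and the others were near zero in wildtype. The bound thus describes mainly genes that ndl1 expressed and wildtype did not. For the 5 it decides nothing, since an order was known for 2 of them and 1 of these lay in the window. In Bif1;Bif4 up to 29 of 41, or 70.7%, could lie in the windows and the question stays open. For the neighbour counts an order was known for 66.3% of tested genes in ndl1 and 66.1% in Bif1;Bif4, also under 80%, and only those genes entered. Around NDL1 20 of 200 neighbours were called in ndl1, 3 of them higher, an odds ratio of 3.38 (Fisher interval 1.995 to 5.43, which takes neighbours as independent) against other genes, with 0 of 67 other blocks of 200 genes reaching that share. In Bif1;Bif4 16 of 200 were called, 10 of them higher, an odds ratio of 1.88 (1.05 to 3.16), a share that 2 of 67 blocks reached. With the window enriched in both, a segment around NDL1 and another source of these calls cannot be told apart. Around BIF1 22 of 200 were called in Bif1;Bif4, 19 of them higher, an odds ratio of 2.70 (1.64 to 4.25) and a share reached by 0 of 67 blocks. In ndl1 the odds ratio was 1.73 (0.845 to 3.20), an interval that holds 2.70, and the difference between the mutants was not tested. A segment of another haplotype around BIF1 remains a candidate explanation for these neighbours, not told apart from another source. Around BIF4 an odds ratio of 0.773 (0.305 to 1.63) decided nothing.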
